A study of Mus musculus with 8 samples.

How the data were processed

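HA-tagged TET1 was profiled by ChIP-seq in 3 mock-treated and 3 nuclease-treated samples of mouse embryonic stem cells. Per the labels' protocols, permeabilised cells were kept for 20 min with or without the nucleases (RNase H1 at 0.2 U/ul, Nuclease S1 at 0.05 U/ul). They were crosslinked in 2 steps, by 2 mM disuccinimidyl glutarate (45 min) and then by formaldehyde at 0.7% (15 min), and the chromatin was sonicated to fragments of 250 bp on average. Chromatin was precipitated with an HA antibody, and libraries were sequenced in paired-end mode for 42 cycles. Input chromatin was pooled over the replicates into 1 input per condition. The 2 input libraries are not analysed here on their own. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

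The submitters' processing notes name Bowtie2 2.2.8, SAMtools 1.3.1, Picard, deepTools 2.4.3, MACS2 2.1.1 and bedtools 2.25.0, and the builds NCBIM37 and mm9. The parameters of these tools are not given in the sources used here. Each deposited file is a list of peaks with 10 columns and no header. The peak names in the files pair each ChIP library with the input of its condition, so the authors called peaks per library. The deposited fold enrichment is a ratio of ChIP coverage over local background at the summit, as the authors' peak caller gave it. The authors' p-value and q-value of each peak are deposited as −log10, and the deposited score is 10 times the −log10 q cut to a whole number. The smallest −log10 q was between 1.30 and 1.31 in each list. Peak numbers in the names run past the length of each list, by 620 to 743 peaks, and those peaks are not analysed here. These fold, p and q values are relative to each library's own background and input. A list therefore shortens if the ChIP signal weakens, if the input is higher at peaks, or if the library is shallower.

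The lists give no fragment counts, but fold and p together fix them. With MACS2's formulas, fold is summit coverage plus 1 over local background plus 1, and p is the Poisson upper tail of the coverage at that background. Whole-number coverages below 700 fragments were tried for each peak. A whole number matched both values within 0.001 of the −log10 p for 99.995% or more of the peaks of every list. For the other 2 to 4 peaks per list a lower bound was used, with the local background set to the genome-wide one. The most frequent local background in a list is the library's genome-wide mean coverage, and summit coverage was divided by it. That quotient, the coverage over background, does not scale with depth and does not use the input. Total fragment numbers are not known, and a median summit coverage of 16 to 18 fragments limits the precision of any single peak.

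The procedures were tested on simulated data first. In 5000 simulated peaks the exact coverage was recovered for 100%. Those peaks were made with the same formulas, so this tests the solving step and not whether the formulas hold for these lists. Coverages as high as those of the strongest peaks were not simulated. In 20000 simulated regions all 300 planted regions of the first group and all 100 of the second were counted. These regions lay well apart and never failed to be detected, so merging of neighbours and partial detection were not tested.

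Groups were taken from the sample titles. Each measure per library was compared by the difference of group means with an exact two-sided permutation test of the 20 label orders, whose smallest p is 0.1, and p-values were adjusted by Benjamini-Hochberg over the 34 measures per library and over the 21 chromosomes. Leaving out a library makes the smallest p 0.2, or 0.1 for the agreement between libraries, which was tested over splits. Peaks of all 6 lists that overlapped or touched were merged into regions, a library counted as having a region if it had a peak in it, and an overlap of 1 bp counted as shared. Counts of regions found in every library of one group only were set against all 10 splits of the libraries. Recovery was measured in deciles of regions by the mean rank, within each list, of the −log10 q in 2 mock libraries. Named regions are the 10 mock-only and the 10 nuclease-only regions of highest mean rank, by a rule fixed before the data were examined, as were the comparisons of peak number, width, covered sequence, agreement, regions of one group only and recovery. That rule names the authors' score, which is 10 times the −log10 q cut to a whole number, and the uncut −log10 q was ranked in its place. The coverage over background, the strongest regions found in all 6 libraries, peaks of 2 kb or wider, the comparison of chromosomes and the tests of depth, a uniform reduction and chromosome X in the closing section were added after seeing the data. Other settings fixed in advance were a q threshold at the pooled median (−log10 q of 6.59), equal list lengths of 62161 peaks, overlap of 50% of the shorter peak, autosomes only, peaks within 500 bp joined, each library left out, and the replicate number as a block. Settings added after seeing the data kept peaks at 10 or 20 times background, or with a local background of at most 2 times the genome-wide level. The labels give the groups the same replicate numbers without saying that a number marks a shared batch.

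Planned analyses of promoters, gene lists and CpG islands needed an mm9 annotation or sequence and were not run, since the gene table at hand is of GRCm38. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.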

Results

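TET1, a dioxygenase that oxidises 5-methylcytosine, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells whose endogenous TET1 carries an HA epitope tag. The series design names the line as E14TG2a, while the sample labels give the strain as C57BL/6N. Before crosslinking, permeabilised cells received either a mock treatment or a 20 min incubation with both RNase H1 and Nuclease S1 (called nuclease-treated here). RNase H1 degrades the RNA strand of RNA-DNA hybrids and Nuclease S1 cleaves single-stranded nucleic acid. Both activities bear on R-loops, structures made of such a hybrid and a displaced DNA strand. No sample received either enzyme alone, and the data hold no measure of R-loops. The comparison is thus of TET1 on chromatin with and without both nucleases, and cannot single out R-loop removal. The data were 6 peak lists, 3 from mock-treated and 3 from nuclease-treated cells, each called by the authors in a single ChIP library against the pooled input of its condition. The mock lists held 83601, 82264 and 73602 peaks in replicates 1, 2 and 3, and the nuclease-treated lists held 70676, 62161 and 74404. The mean fragment coverage of the genome, recovered from the lists as the background level of the peak caller, was 2.253, 2.232 and 2.131 fragments in mock replicates 1, 2 and 3 and 2.105, 1.929 and 2.239 in the nuclease-treated replicates (exact two-sided permutation p = 0.3). Where coverage is given below as times background, it is the summit coverage of a peak divided by this level in its own library. Positions are on mm9. No gene annotation of that build was used here, so regions are named by position only and whether they lie in genes, exons or promoters is not reported.

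TET1 peaks were fewer, and strong peaks much fewer, in the nuclease-treated cells. Mock lists held 79822 ± 5428 peaks and nuclease-treated lists 69080 ± 6276 (SD, n = 3 each), a difference of 13.5%. The groups overlapped, since mock replicate 3 had fewer peaks than nuclease-treated replicate 3. The difference of -10742 peaks became -19333 with a stricter q-value threshold and -17277 without peaks of high local background, but both settings depend on the local background, which was higher in the nuclease-treated lists, and the q value depends on the ChIP coverage as well; the parts were not separated. Peaks whose summit coverage reached 20 times the library's own background numbered 6382 ± 198 in mock and 1469 ± 74.2 in nuclease-treated libraries (SD, n = 3 each), 0.230 of the mock number. At 10 times background the numbers were 27492 ± 1240 and 17622 ± 382 (SD, n = 3 each). Broad peaks of 2 kb or wider were also fewer, at 1713 ± 96.6 against 859 ± 136 (SD, n = 3 each), and the sequence under peaks covered 49.1 ± 2.37 Mb against 38.6 ± 3.85 Mb (SD, n = 3 each). For strong peaks, broad peaks and covered sequence, all 3 nuclease-treated libraries lay below all 3 mock libraries, which gave an exact two-sided permutation p = 0.1 for each, the smallest value that 3 libraries against 3 can reach; for the number of all peaks the exact permutation p was 0.2. Adjusted over the 34 measures compared per library (Benjamini-Hochberg), the exact permutation p = 0.1 became 0.142. Median peak width was 448 ± 14.1 bp in mock and 424 ± 5.51 bp in nuclease-treated lists (SD, n = 3 each), but under a stricter q-value threshold the direction turned, with the nuclease-treated lists 8 bp higher (exact permutation p = 0.6), and among peaks of at least 10 times background the difference was -69 bp.

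**Figure D1:**
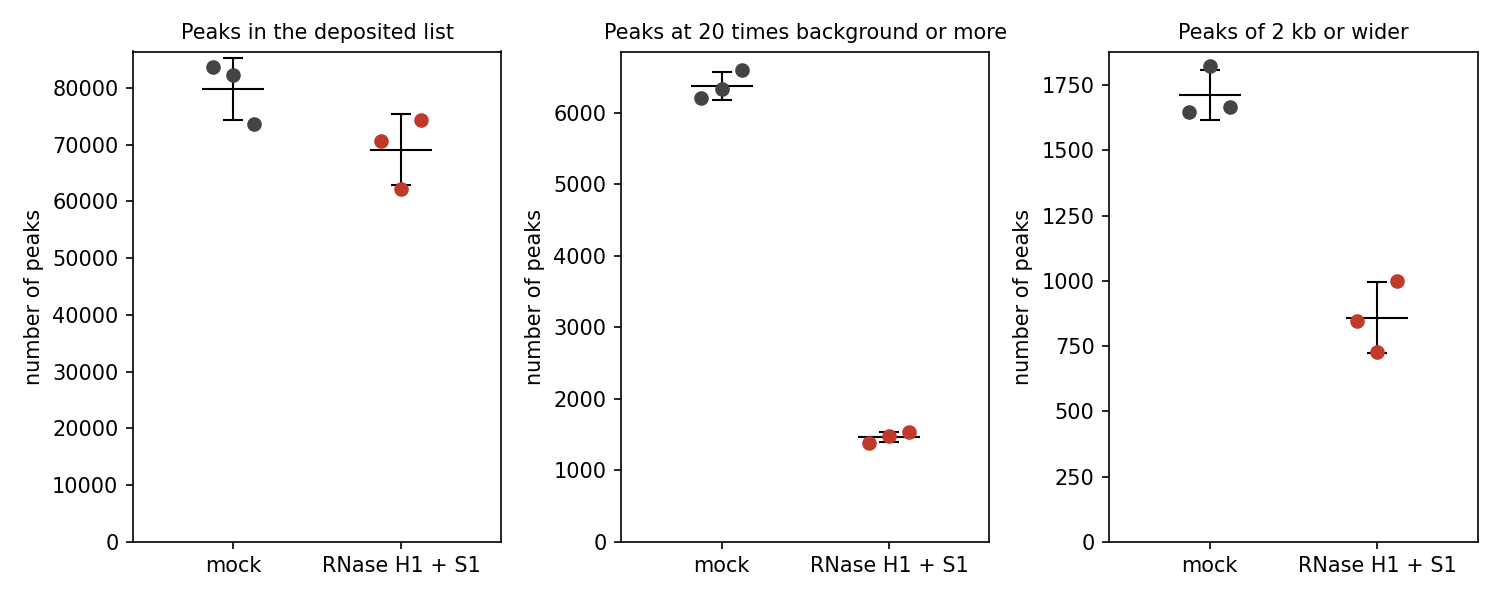
Number of peaks per library (y axes, from 0) in the deposited lists, at a summit coverage of 20 times background or more, and at a width of 2 kb or more. Points are the 3 libraries of each group, and bars are the mean ± SD. The groups overlap in the left panel and are apart in the other panels, where mock means are 6382 and 1713 and nuclease-treated means are 1469 and 859.

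The fold enrichment that the authors' peak caller gave each peak, which describes a peak within its own list, was lower in the nuclease-treated lists. Its median per list was 5.26 ± 0.0594 in mock and 4.40 ± 0.0696 after treatment (SD, n = 3 each), and the lists held 8952 ± 262 and 1013 ± 96.2 peaks with a fold of 10 or more (SD, n = 3 each). Both the ChIP coverage and the local background entered this fold. The median local background at peaks was 2.54 ± 0.0592 fragments in mock and 2.98 ± 0.208 in nuclease-treated lists (SD, n = 3 each), and 27.5 ± 0.472% of mock peaks against 12.3 ± 2.05% of nuclease-treated peaks had a local background no higher than the genome-wide level (SD, n = 3 each). Every one of these differences separated the 3 libraries of each group (exact two-sided permutation p = 0.1). The 3 libraries of a group shared 1 pooled input, so the local background is in effect unreplicated, whereas coverage over the genome-wide background does not use the input. Counts of peaks by that coverage still depend on the input, since only called peaks are counted. Without peaks of high local background, the difference at 10 times background went from -9871 to -13685 peaks, and that at 20 times stayed at -4912.

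**Figure D2:**
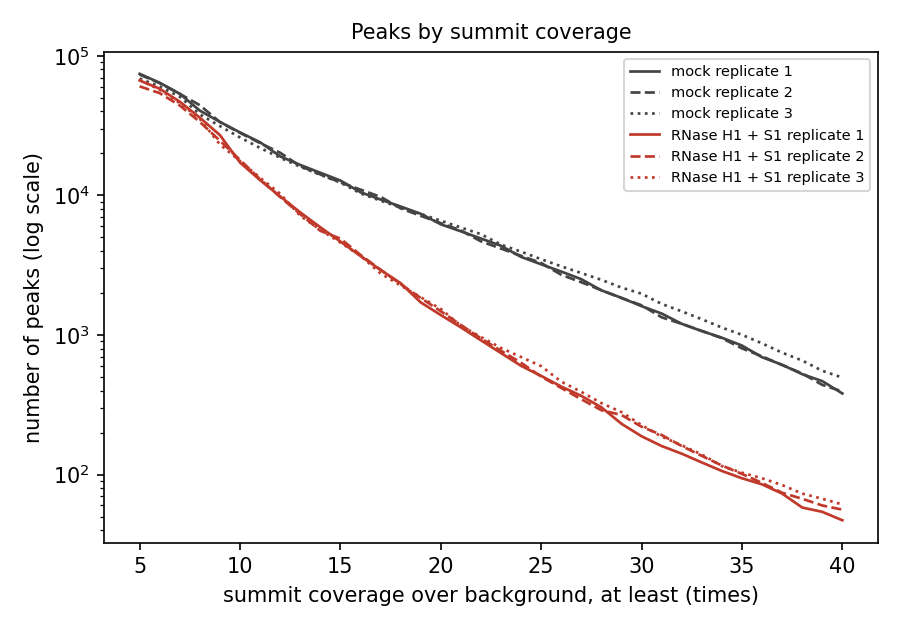
Number of peaks (y axis, log scale) with a summit coverage of at least the given multiple of the library's own background (x axis), 1 line per library. The distance between the groups widens with coverage, from 27492 against 17622 peaks on average at 10 times background to 6382 against 1469 at 20 times.

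Most strong TET1 regions had a peak after treatment as well, and the share of regions without one was higher at weak and intermediate strength. Among regions with a peak in 2 mock libraries, the left-out mock library had a peak in 86.7 ± 3.40% and the nuclease-treated libraries in 73.3 ± 3.59% (SD, n = 3 each). The difference of 13.5 percentage points gave an exact two-sided permutation p = 0.1, and the next highest of the 20 label orders reached 6.27 points. With lists of equal length the difference was 11.5 points. Without peaks of high local background it was 23.5 points, a filter that removes more peaks from the nuclease-treated lists because their local background was higher. Peak calls also depend on the local background, for which the libraries of a group shared a pooled input. The permutation test therefore takes the libraries as more independent than they were, here and in the agreement and region counts below. How much of the gap came from the input was not tested. In the strongest decile of regions, ranked by the authors' q value within each list, 99.9 ± 0.0328% were recovered in the left-out mock library and 99.1 ± 0.139% after treatment (SD, n = 3 each). The gap was widest in the fifth decile from the bottom, where 89.0 ± 4.99% and 68.8 ± 4.68% were recovered (SD, n = 3 each), and it was 11.4 points in the weakest decile. Recovery does not mean unchanged coverage, since a strong region can lose coverage and still be called. At regions of 20 to 30 times background in 1 mock library, 98.5% had a peak after treatment. There 0.629 of the coverage above background in the other 2 mock libraries was left.

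**Figure D3:**
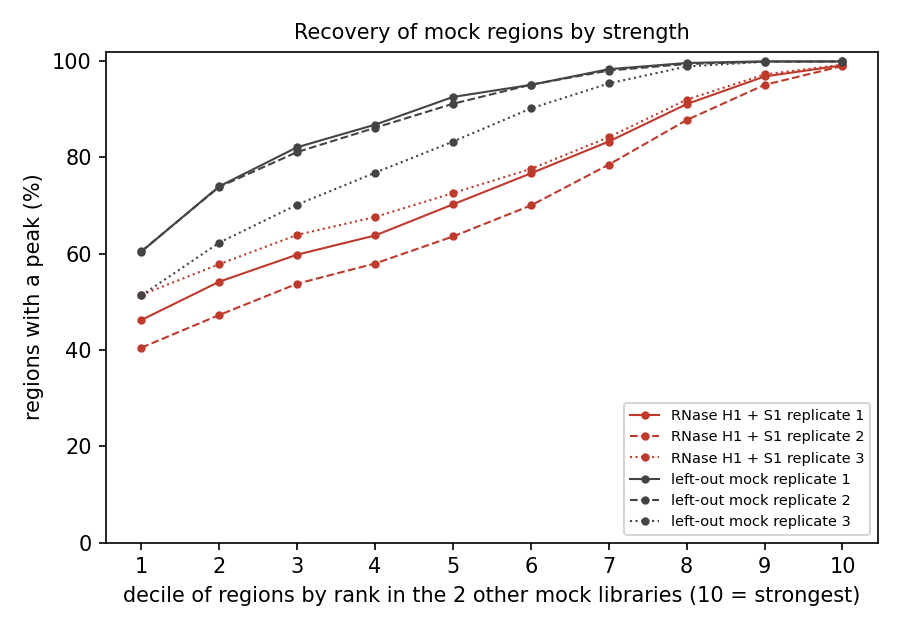
Percent of regions with a peak (y axis) in the left-out mock library (grey) and in each nuclease-treated library (red), by decile of regions ranked in the other 2 mock libraries (x axis, 10 the strongest). The mean gap was 20.2 percentage points in decile 5 and 0.807 in decile 10.

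Mock libraries resembled one another more than they resembled the nuclease-treated libraries, whereas the nuclease-treated libraries did not stand apart as a set. The Jaccard index, the bases shared by a pair of lists over the bases in either, averaged 0.566 between mock libraries, with a range of 0.563 to 0.570. It averaged 0.456 between nuclease-treated libraries, with a range of 0.452 to 0.464, and 0.462 between the groups, with a range of 0.442 to 0.480. Pairs within groups exceeded pairs between groups by 0.0488 (exact two-sided permutation p = 0.1 over the 10 splits of the 6 libraries). Leaving out mock replicate 1, 2 or 3 reduced this to 0.0198, 0.0200 or 0.0242, with an exact permutation p = 0.3 for each, where 0.1 was the smallest possible. Leaving out nuclease-treated replicate 1, 2 or 3 gave 0.0760, 0.0700 or 0.0830. The mean within groups pools all pairs, so without a mock library most of its pairs are nuclease-treated ones, which agreed less. Without a nuclease-treated library most are mock pairs. These omissions therefore cannot tell how far the difference rests on any single library. The difference was 0.109 with a stricter q-value threshold and 0.113 among peaks of at least 10 times background. Another mock library overlapped 73.2% of a mock library's peaks on average and a nuclease-treated library 60.4%. For nuclease-treated peaks the order was reversed, with 72.4% overlapped by a mock library and 65.2% by another nuclease-treated library. Over all pairs, the share within groups exceeded that between groups by 2.81 points. The difference of 12.8 points for mock peaks became 10.4 with lists of equal length, 29.9 with the stricter threshold and 26.3 at 10 times background.

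Merging the 6 lists gave 137027 regions, of which 29613 had a peak in every library and 46544 in a single library. Of the 48273 regions with a peak in all 3 mock libraries, 3222 (6.67%) had none in any nuclease-treated library. In the other direction, 575 of the 34189 regions found in all 3 nuclease-treated libraries (1.68%) had no mock peak. The mock-only count exceeded that of every other split of the libraries, the highest of which was 1308, and the nuclease-only count did not. Mock lists were longer on average, so sides made mostly of mock libraries are no like comparison for the nuclease-only count. No other split keeps together the libraries that share a pooled input, so the comparison of splits does not set the input apart from the treatment. Mock-only regions had lower coverage than regions found in all 6, with a median in the mock libraries of 7.70 against 12.7 times background. Their median width was 468.5 bp, against 1038 bp for regions found in all 6. A region found in all 6 merges more peaks, which widens it, so these widths are not like for like. Single peaks of the mock lists had a median width of 448 bp and a median coverage of 8.17 times background, averaged over lists. Only 52 of the mock-only regions reached 15 times background in mock, out of 11851 regions of that strength in all 3 mock libraries. The nuclease-only regions had lower coverage than regions found in all 6 as well. Their median coverage in the nuclease-treated libraries was 6.67 times background, against 10.0 for regions found in all 6. Their median width was 507 bp, where single peaks of the nuclease-treated lists had a median of 424 bp on average. No single region can pass a test when presence in 3 libraries is set against absence in 3, and no call is made for one. Leaving out 1 library, which loosens the requirement, gave 4614 to 6514 mock-only and 895 to 2163 nuclease-only regions, over 1.5 times the full counts for each library left out except nuclease-treated replicate 2 in the mock-only count.

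The mock-only regions of highest rank lay on several chromosomes. The top region, on chromosome 7 from 137977876 to 137978156, had 107 ± 7.02 times background coverage in mock (SD, n = 3) over a local background 7.61 times the genome-wide level. The second, on chromosome 14 from 62667760 to 62668053, had 52.1 ± 6.02 times background (SD, n = 3) over a local background at the genome-wide level. Next were chromosome 6 from 128374525 to 128375057, at 24.3 ± 1.64 times background, and chromosome 16 from 98130603 to 98130936, at 21.8 ± 3.43 (SD, n = 3 each). On chromosome 11, the region from 98261102 to 98261894 had 22.4 ± 0.934 times background and that from 42022158 to 42022485 had 19.2 ± 3.64 (SD, n = 3 each). The widest of the 10 was a 1024 bp region on chromosome 17 from 57386141 to 57387164, at 18.6 ± 1.37 times background (SD, n = 3). The other 3 lay on chromosome 2 from 165372574, chromosome 4 from 107562171 and chromosome 9 from 64026972, at 18.7 ± 2.32, 18.9 ± 2.81 and 17.5 ± 2.04 times background (SD, n = 3 each).

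Of the nuclease-only regions, 5 reached 15 times background after treatment. The leading pair had a local background over 20 times the genome-wide level: chromosome M from 15408 to 16057, at 103 ± 1.19 times background coverage but a fold of only 4.28 ± 0.0487, and chromosome 8 from 73956386 to 73957065, at 97.6 ± 3.07 times background and a fold of 3.88 ± 0.165 (SD, n = 3 each). Chromosome 11 from 42881775 to 42882087 had 16.6 ± 4.18 times background (SD, n = 3) over a local background at the genome-wide level. On chromosome 7, a 3140 bp region from 12600218 to 12603357 had 16.4 ± 2.92 times background and a second from 46610101 to 46610550 had 15.1 ± 1.82 (SD, n = 3 each). The other 5 of the top 10, on chromosomes 14, 15, 8, 1 and 7, lay between 8.29 and 10.4 times background.

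Peaks on chromosome X made up a smaller part of the nuclease-treated lists. Chromosome X held 1.77 ± 0.0974% of mock peaks and 1.53 ± 0.0686% of nuclease-treated peaks (SD, n = 3 each), or 1411 ± 44.0 against 1059 ± 129 peaks. Chromosome 3 likewise held 3.68 ± 0.0371% and 3.45 ± 0.0775%, while chromosome 11, which carried the most peaks in every library, held 9.39 ± 0.0181% and 9.87 ± 0.284% (SD, n = 3 each). Of 21 chromosomes compared, the libraries of the groups did not overlap for 10, with the nuclease-treated share lower for 6 and higher for 4. Chance gives 10% of chromosomes without overlap. The chromosomes are not independent of one another, since the shares of a library add up to its whole list. The same libraries and pooled inputs also lie behind all of them, so the number without overlap is a description only. For each chromosome without overlap, the exact two-sided permutation p was 0.1, and 0.21 after Benjamini-Hochberg adjustment over the 21. When peaks of high local background were left out, the chromosome X difference shrank from -0.241 to -0.0815 percentage points (exact permutation p = 0.4).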

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

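This result was noticed in the data. The mitochondrial genome, which is outside the chromosomal comparison, carried a peak in 3 of 3 nuclease-treated lists and in none of the 3 mock lists (exact two-sided permutation p = 0.1, and 0.142 adjusted over 34 measures). It lay on chromosome M from 15408 to 16057, with 103 ± 1.19 times background coverage and a fold of 4.28 ± 0.0487 (SD, n = 3). Its mean local background was 49.7 fragments, 23.8 times the genome-wide level. The lists of a group shared a pooled input for this background, and the peak was picked after its presence had been seen. The p-value therefore measures no spread between independent samples. The mock lists give no value for positions without a peak, so the coverage there in mock cells is unknown and no explanation was tested. The nuclease-only region on chromosome 8 from 73956386 to 73957065 shared these features, with a local background 24.8 times the genome-wide level.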

How the results depend on the processing

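Of 164 recomputed values, 145 kept their direction and side of the threshold or stayed within 1.5 times of the reported count, 18 counts moved by more and 1 reversed; no test can pass 0.05 with 3 libraries against 3, so keeping its side says little. The reversal was the median peak width, whose difference became 8 bp with a stricter q threshold; the cause was not tested. With that threshold the mock-only regions numbered 5510 and the nuclease-only regions 69. Equal list lengths gave 959 nuclease-only regions and 2353 mock-only regions, a coverage of at least 10 times background gave 19 nuclease-only regions, and leaving out peaks of high local background gave 6975 mock-only regions; the last 2 settings were chosen after seeing the data. The stricter threshold and the filter on local background both depend on a local background that was higher in the nuclease-treated lists, and how much of the larger differences under them comes from it was not tested. Leaving out 1 library each gave 4614 to 6514 mock-only and 895 to 2163 nuclease-only regions, since fewer libraries had to share a region or lack it. Mock-only regions outnumbered nuclease-only regions under every alternative run for them. Over the same omissions, the difference in peak number ranged from -13852 to -7282 (-19333 with the stricter threshold, -17277 without peaks of high local background), that in covered sequence from -12.4 to -8.54 Mb, that in recovery from 11.5 to 15.0 percentage points (23.5 without peaks of high local background), and that in peaks at 20 times background from -4997 to -4804. The replicate numbers gave no clear pairing of the libraries. Deviations from the group means over regions found in all 6 libraries correlated at 0.0134, -0.00488 and 0.0379 for the same number. Mock replicates 1 and 3 correlated best with their own number, and mock replicate 2 correlated better with another number. All pairs lay between -0.0417 and 0.0379, too weak to show or exclude a pairing. With the replicate block, the difference of -10742 peaks gave an exact sign-flip p = 0.5, and no call changed. In the weakest decile a left-out mock library recovered 57.4% of regions; depth was not varied, so what depth limits was not measured. Settings for promoters, gene lists and CpG islands were not run.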

Other observations

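The test of depth was chosen after the values it bears on had been seen, as were the regions named here; the count over other splits was fixed in advance, but the outcome it was to be read against was written down afterwards. The tests of a uniform reduction and of chromosome X were set before their own values were seen, but after the coverage left by strength and the loss and coverage per chromosome had been looked at. Across the 29613 regions called in all 6 libraries, median summit coverage was 12.8 ± 0.163 times background in mock and 10.1 ± 0.281 after treatment (SD, n = 3 each; exact two-sided permutation p = 0.1). All 3 nuclease-treated libraries lay below all 3 mock libraries at 13225 of these regions (44.7%) and above them at 411 (1.39%), where chance gives 5% in each direction. Where strength was read in 1 mock library and compared with the other 2, the coverage above background that was left after treatment was 0.629 ± 0.00237 of mock at regions of 20 to 30 times background and 0.624 ± 0.00679 at 30 to 60 times (SD, n = 3). At 15 to 20 times it was 0.680 ± 0.00327 and at 10 to 15 times 0.781 ± 0.00775 (SD, n = 3), but there only 94.8% and 83.8% of the regions had a peak after treatment, and those without one are not in the ratio. The SDs of these ratios cover the 3 nuclease-treated libraries, each set against the same mock libraries. They leave out the spread between mock libraries.

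Of the 10 regions of highest rank in all 6 libraries, a few are given here, and differences between them were not tested. The ratio of the mean coverage after treatment to that in mock ranged from 0.595 to 1.00 over the 10, and from 0.595 to 0.913 over the 6 of them under 600 bp, where some coverages are lower bounds. Over all 35 regions of more than 60 times background in mock, the median ratio was 0.716. A 4353 bp region on chromosome 1 from 88421244 to 88425596 had 74.5 ± 1.28 times background coverage in mock and 57.0 ± 4.31 after treatment, and a 2060 bp region on the same chromosome from 180266318 to 180268377 had 86.5 ± 5.59 and 63.6 ± 3.23 (SD, n = 3 each). A 346 bp region on chromosome 8 from 37306134 to 37306479 had at least 84.6 ± 6.24 in mock, where the coverage of 1 library is a lower bound, and 50.3 ± 3.00 after treatment (SD, n = 3 each). On chromosome 17 from 76612822 to 76613969 the values were 65.9 ± 15.3 and 59.3 ± 8.66 (SD, n = 3 each). On chromosome X from 125975515 to 125976656 the values were 74.4 ± 13.5 and 74.6 ± 10.8 (SD, n = 3 each); for the regions on chromosomes 17 and X the difference lay within the spread between libraries.

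Regions of 20 to 60 times background also differed by width. Those with a mock peak under 1000 bp were left with 0.616 ± 0.00142 of the mock coverage above background, those of 1000 to 2000 bp with 0.626 ± 0.00536, and those of 2000 bp or more with 0.654 ± 0.00608 (SD, n = 3 nuclease-treated libraries each). As for the classes of coverage above, these SDs leave out the spread between mock libraries. All 3 nuclease-treated libraries had a higher ratio in the widest class than any had in the narrowest; the difference was not tested, and these are the same libraries.

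The lower coverage after treatment at regions called in all 6 libraries is not explained by shallower sequencing alone. Coverage divided by each library's own background was still 0.783 of mock there. The median of this quotient over all peaks of a list was 8.17 ± 0.245 in mock and 7.99 ± 0.360 after treatment (SD, n = 3 each, exact two-sided permutation p = 0.6). Those medians are taken over different peaks in each list. This quotient does not use the input. In the fold enrichment, which does, the ChIP coverage made up 63.7% of the mean log2 change at these regions, -0.36 of -0.57, and the higher local background 36.3%. A single reduction of the same size at every region, as a less efficient immunoprecipitation might give, predicted that log2 ratios of library pairs without a shared library would be uncorrelated across strong regions. Over 18 such pairings of 5958 to 6285 regions, the median Pearson r was 0.294 (range 0.198 to 0.445, median Spearman rho 0.272). It was 0.397 to 0.445 in pairings over mock replicates 1 and 2, and 0.198 to 0.304 in those with mock replicate 3. Part of the correlation may thus be shared between mock libraries. The values speak against a uniform factor as the whole cause only if the libraries of a group vary independently, which was not tested. Regions are also not independent replicates, and a bias of sequence or fragment length between treatments could give the same correlation. The nuclease treatment itself, with both enzymes together and no spike-in among the labels, stays open as an explanation, as does a lower yield that acts on top of differences between regions.

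The smaller share of chromosome X may reflect its weaker peaks. Regions on chromosome X called in all 3 mock libraries had a median coverage of 8.84 times background against 10.3 on autosomes, and nuclease-treated libraries recovered them less often by 2.23 percentage points on average. Against autosomal regions of the same mock coverage, they were recovered more often, by 2.90 ± 0.792 points (SD, n = 3 libraries). The deficit was thus gone at equal coverage, but the difference lay beyond the 2 points set in advance as no difference, in the opposite direction, so this explanation is left open.

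Chance in how the libraries were grouped cannot be judged with 10 splits. The real split gave 3222 mock-only regions and the highest other 1308, so 1 of 10 splits reached that number. For the 575 nuclease-only regions, all 10 splits had a side with as many. In most other splits that side held 2 mock libraries, whose lists were longer on average, so it is no like comparison. Sides with 1 mock and 2 nuclease-treated libraries gave 281 to 692 regions.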
